A study of Mus musculus with 2 samples.

How the data were processed

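Total RNA was taken from live GFP-positive cells that had been released from dorsal mouse skin with collagenase and trypsin, sorted by flow cytometry and collected in a phenol reagent, per the labels' protocols. Ribosomal RNA was removed by hybridization, so RNAs without a poly(A) tail remain in the libraries. Paired-end reads of 150 bases were sequenced on a NovaSeq from libraries made with the NEBNext Ultra II RNA kit, per the labels' protocols. No strand-marking version of the kit is named there, and the strand setting of the counting is not given in the sources used here. Whether reads of a gene and of an overlapping antisense gene were counted apart is therefore unknown. The deposited files give 1 raw count per gene and the gene length in bases. The counts were made with featureCounts on genome build mm39, per the submitters' processing notes. The aligner, the annotation release and the treatment of reads with several mapping places are not given in the sources used here. They bear on near-identical genes such as Hspa1a and Hspa1b, the alpha globins Hba-a1 and Hba-a2, Krt6a and Krt6b, histones and mitochondrial genes, whose separate counts are uncertain.

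Both files list the same 50559 genes with the same lengths, of which 17803 had no count in either library, and no row lacked a gene name. Both samples form 1 group, and their replicate numbers are those in the labels. No genome of build mm39 was used here, so no coordinates are given. The reference at hand was GENCODE release M21 on GRCm38, and only its transcript sequences were used, for GC content and for sequence similarity. Symbols are those of the files. All members of the fixed gene lists were found except 1 (Tcrg-C1), and the name pattern fixed for mitochondrial genes matched only 2 rRNA genes, mt-Rnr2 and mt-Rnr1, because the other mitochondrial genes carry plain names in these files. Those 2 had mean levels of 23.5 and 11.4 CPM, and the 37 mitochondrial genes were taken by name instead.

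CPM were computed from the total of all counts, and TPM from the counts and the deposited length. A gene was called detected at 1 CPM in both libraries, which is 36.7 counts in replicate 1 and 33.5 counts in replicate 2. Agreement was measured on log2(CPM + 0.5) over genes with 10 or more counts in total. Its 95% interval came from 1000 bootstrap draws over genes. The coefficient of variation between libraries came from edgeR with an intercept-only design and TMM factors. The ratio of each gene between the libraries was tested with the exact two-sided binomial test against the ratio of totals, with Benjamini-Hochberg adjustment at 0.05. Intervals on ratios are exact (Clopper-Pearson) 95% intervals. These, and the floor of 3 counts for a gene without counts, cover counting error only, since reads without molecular identifiers are not independent molecules. edgeR's exact test, with the dispersion of an intercept-only fit over all 23690 tested genes, was the alternative that includes the spread between libraries. Because that dispersion is estimated from the same 2 libraries, real differences enlarge it.

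Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Named are the 15 genes with the highest mean CPM, the 3 highest and the lowest member of each list, all members of the polymerase II and sex-linked lists, members without a count, and the 10 genes with the largest ratio in each direction among those past the binomial test at a mean of 10 CPM or more. Most polymerase II subunits are given as a range, and some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen, as were 8 further lists. For each of 29 lists with 5 or more members at 10 or more counts, the median log2 ratio was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. This places the list within these libraries and gives no p-value. Members of a list that are regulated together spread more widely than random genes do. Nuclear copies of mitochondrial genes were searched with blastn among the reference transcripts, which do not hold unannotated sequence. The self-tests used simulated libraries of the real depths. On 23690 genes with sampling noise only, the binomial test recovered 91% of genes at a log2 change of 0.3 and 100% at 1, with 16 false calls. edgeR's exact test was run on as many genes with a simulated coefficient of variation of 15%. It recovered 14% at a log2 change of 1 and 97% at 2, with 1 false call, so a difference of 2-fold is mostly missed by it. The real test ran at a coefficient of variation of 22.7%, and its recovery at that spread was not measured. In this and the binomial self-test, the changed genes were drawn from those with higher counts. In the test of the list step on scrambled ratios, the list shifted by -0.5 fell at the 0.01 percentile, and 2 unshifted lists lay outside. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 (size factors only) and blastn 2.17.0. The alternatives tried were other scalings, filters, pseudocounts, length scaling, thinning of the deeper library and leaving out each library.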

Results

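The RNA content of keratinocytes sorted from mouse dorsal skin was measured by bulk RNA sequencing. The mice carried floxed Polr2b with GFP, where Polr2b encodes a large subunit of RNA polymerase II, and a Cre recombinase under the keratin 14 promoter, which is active in the basal epidermis and its follicular lineages. Skin was taken at postnatal day 21, in telogen, the resting phase of the hair follicle. The series holds 1 group of 2 replicate libraries, and its stated purpose was to relate steady-state RNA to nascent RNA. The nascent RNA data were not analysed here, so the comparisons below are of gene groups within the sorted cells and of the 2 libraries with each other. Replicate 1 held 36692204 counts on 30840 genes and replicate 2 held 33489967 counts on 28921 genes. Levels are given as CPM, the count of a gene scaled to a common library total, as mean ± SD with n = 2 unless stated otherwise. With 2 libraries a two-sided sign-flip test of a level cannot give a p below 0.5, so levels are described with their spread and without a p-value.

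The first question was which cells the sorted fraction represented. Basal epidermal genes were abundant, with Krt5 at 5123 ± 1593 CPM, its filament partner Krt14 at 2639 ± 759 CPM and the hemidesmosomal collagen Col17a1 at 2628 ± 459 CPM. All 12 basal genes passed 10 CPM in both libraries. Genes of cell-cell junctions stood as high, with the desmosomal linker Dsp at 3499 ± 719 CPM, Perp at 1516 ± 248 CPM and plakoglobin (Jup) at 1247 ± 303 CPM. Of the 11 junction genes, 10 passed 10 CPM in both libraries, and Dsc2 was the exception at 7.29 ± 0.678 CPM. Suprabasal transcripts were present too. The spinous keratins Krt10 and Krt1 reached 2296 ± 997 CPM and 1226 ± 825 CPM, and the transcription factor Klf4 reached 1085 ± 87.7 CPM. The metallothionein Mt4 was the lowest of the 10 spinous genes at 6.74 ± 1.70 CPM. Transcripts of the granular and cornified layers were scarcer, with a list median of 22.3 CPM over 13 genes. Their highest member was Sprr1a at 146 ± 19.4 CPM, followed by the cross-linking enzyme Tgm1 at 34.9 ± 4.49 CPM, and the cornified envelope gene Lce1b stood at 1.66 ± 0.268 CPM.

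The median basal level exceeded the median spinous level by 0.46 ± 0.32 on the log2(CPM + 0.5) scale, with 0.69 in replicate 1 and 0.23 in replicate 2. This order depended on gene length. Scaled by the deposited gene length (TPM), the same difference was -0.97 ± 0.14, with list medians of 181 TPM for basal and 344 TPM for spinous genes.

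Genes of the resting follicle stood above those of the hair shaft. Of 12 genes of the bulge, the stem cell region of the resting follicle, all passed 1 CPM in both libraries. Their median was 68.0 CPM, at the 78.6 percentile of the detected genes, beside 98.5 for the basal list. Krt15 led at 3142 ± 1027 CPM, and is also expressed by basal epidermis. The transcription factors Runx1 and Nfatc1 stood at 238 ± 29.1 and 228 ± 2.42 CPM, and the growth factor Fgf18 was lowest at 1.23 ± 0.0389 CPM. The 7 upper follicle genes all passed 10 CPM, with Krt17 at 546 ± 47.9 CPM, Krt79 at 306 ± 57.0 CPM and Plet1 at 199 ± 52.9 CPM. In contrast, 4 of 12 genes of the hair shaft and inner root sheath reached 1 CPM in both libraries and none reached 10 CPM in both. Hoxc13, a regulator of hair keratins, was highest at 12.8 ± 5.32 CPM, followed by the inner root sheath protein gene Tchh at 5.75 ± 1.62 CPM. The hair keratin Krt85 stood at 0.206 ± 0.249 CPM. The bulge median exceeded the hair shaft median by 5.88 ± 0.61 (log2), which was 58.9-fold, although the size moved with the pseudocount because the hair shaft genes were near the floor. The counts do not show which cells of the fraction made the RNAs of the bulge list. Fibroblast and myeloid genes were abundant in the fraction too, as described below. Sebaceous genes ranged from the desaturase Scd1 at 819 ± 210 CPM to its relative Scd3 at 0.343 ± 0.0221 CPM, and 5 of 11 passed 10 CPM in both libraries. Merkel cell genes were near the floor. Of 7, 2 reached 1 CPM in both libraries, and Atoh1 had no count in either, which allows up to 0.0818 CPM in replicate 1 and 0.0896 CPM in replicate 2.

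Signalling genes tied to the hair cycle were measured at moderate levels. Of 9 genes linked to telogen quiescence, 7 passed 10 CPM in both libraries, with Foxp1 at 295 ± 45.1 CPM and Id2 at 105 ± 26.5 CPM. The bulge list shares 3 of these 9 genes, so the 2 lists are not independent. Of 11 genes of Wnt, Shh and Eda signalling, 9 passed 10 CPM, with Wnt7b at 78.5 ± 17.1 CPM and the Hedgehog effector Gli2 at 60.1 ± 24.1 CPM, while the Wnt antagonist Dkk4 stood at 0.346 ± 0.320 CPM.

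**Figure D1:**
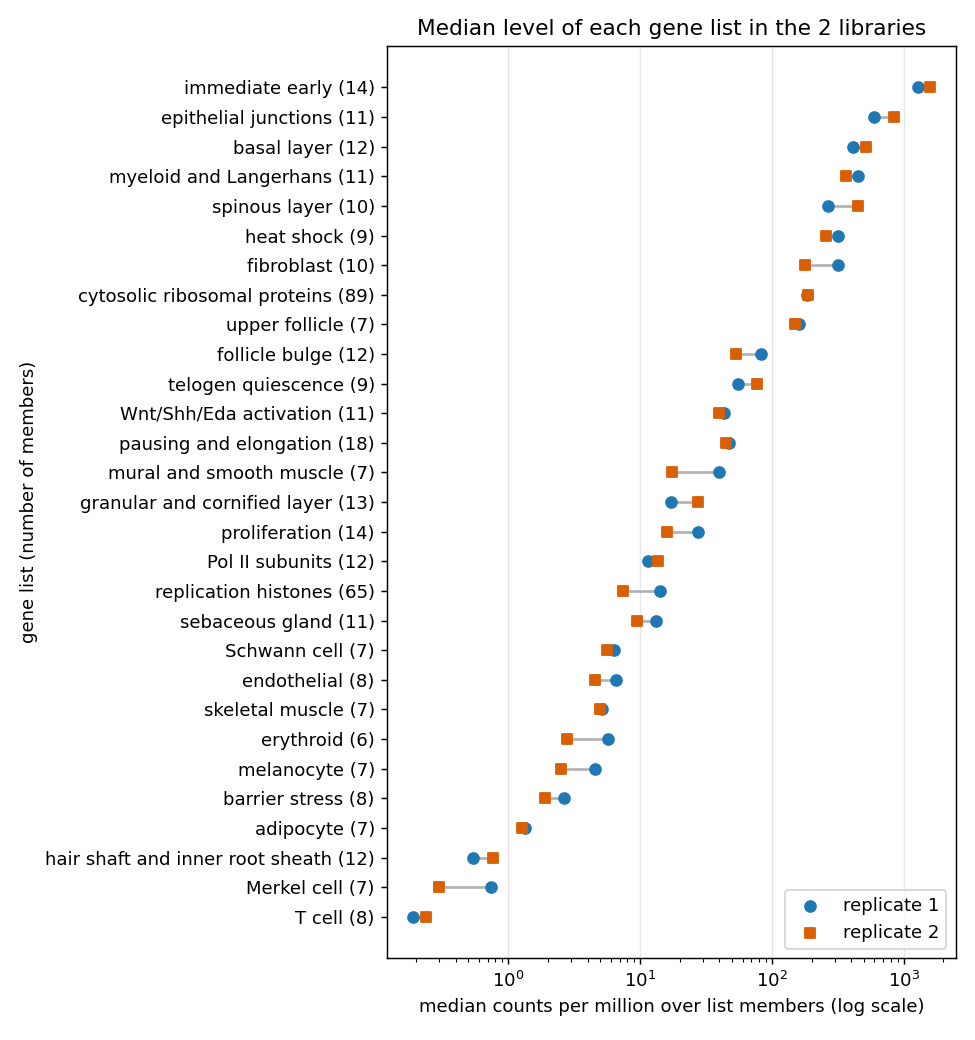
Median CPM over the members of each gene list (log axis) in replicate 1 (circles) and replicate 2 (squares), with the number of members in brackets and a line joining the libraries. The immediate early list is highest at 1423 CPM, the junction, basal and spinous lists stand at 715, 450 and 356 CPM, the myeloid list lies between the basal and spinous lists at 364 CPM, and the fibroblast list below them at 248 CPM.

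Transcripts of dermal and immune cells were also abundant in the sorted fraction. Fibroblast genes included type I and type III collagen, with Col1a1 at 4104 ± 2099 CPM, Col3a1 at 3352 ± 1476 CPM and Col1a2 at 1721 ± 854 CPM. All 10 fibroblast genes passed 10 CPM in both libraries, with Mfap5 lowest at 24.8 ± 12.3 CPM. Macrophage genes were abundant too. The mannose receptor Mrc1 was at 2064 ± 93.5 CPM, lysozyme (Lyz2) at 1702 ± 449 CPM and the complement gene C1qb at 1210 ± 5.61 CPM, and 10 of the 11 myeloid genes passed 10 CPM. The exception was Cd207, the langerin gene of Langerhans cells, at 4.59 ± 2.48 CPM. The medians of the myeloid and fibroblast lists lay at the 97.8 and 95.9 percentiles of the 15833 detected genes, beside 98.5 for the basal list. The 10 fibroblast genes held 1.45% of counts in replicate 1 and 0.722% in replicate 2, and the 11 myeloid genes 0.762% and 0.798%.

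Markers of other skin cell types were lower than those of fibroblasts and macrophages. The endothelial list had a median of 5.47 CPM, with Cdh5 highest at 20.4 ± 7.39 CPM. The mural and smooth muscle list had a median of 30.5 CPM, with the pericyte gene Rgs5 at 33.8 ± 22.9 CPM, while Tagln had 0 counts in replicate 1 and 5 in replicate 2. Medians were 5.04 CPM for skeletal muscle, 6.01 CPM for Schwann cells, 4.27 CPM for erythroid cells, 3.53 CPM for melanocytes and 1.31 CPM for adipocytes. T cell genes had a median of 0.187 CPM, with Thy1, which fibroblasts also express, at 28.2 ± 8.40 CPM and no count for Trdc in either library. Over all 78 genes of the 10 non-epithelial lists, the median lay 6.01 ± 0.78 (log2) below that of the 33 basal, spinous and junction genes, or 64.3-fold. The difference was 5.45 in replicate 1 and 6.56 in replicate 2, and 4.73 with TPM. The pooled value is no measure of purity. The myeloid and fibroblast list medians, at 364 and 248 CPM, stood beside 356 CPM for the spinous list and 450 CPM for the basal list.

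RNA polymerase II genes were examined because the genotype modifies Polr2b. Polr2b had 83.4 ± 6.99 CPM, and the counts do not separate RNA of modified and unmodified alleles. The largest subunit gene, Polr2a, had 436 ± 19.0 CPM. The other 10 subunit genes lay between Polr2k at 2.75 ± 0.769 CPM and Polr2c at 19.1 ± 0.0577 CPM. Scaled by length the subunits lay between Polr2h at 8.16 TPM and Polr2a at 161 TPM, with Polr2k at 10.9, Polr2j at 51.7 and Polr2b at 54.2 TPM. All 18 pausing and elongation genes passed 10 CPM in both libraries. The elongation factors Supt6 and Supt5 stood at 197 ± 17.4 and 167 ± 14.9 CPM. Leo1 of the Paf1 complex was lowest at 12.9 ± 0.00591 CPM. The median log2 ratio of replicate 2 over replicate 1 was 0.10 for the subunits and 0.05 for the elongation genes, both inside the range of matched random lists.

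The list with the highest median was that of immediate early genes, transcription factors and signalling regulators that respond within minutes to stimuli. Egr1 had 4916 ± 438 CPM, Fos 3594 ± 1.04 CPM and Fosb 3549 ± 366 CPM, and Egr1, Fos and Fosb were among the 15 most abundant genes. The lowest of the 14 was Ier3 at 318 ± 7.17 CPM, and the list held 2.55 ± 0.255% of all counts. The cells had been released with enzymes and sorted before their RNA was taken. Undisturbed skin was not measured, so the level of these genes in the tissue is unknown. Heat shock genes had a median of 309 CPM, led by the constitutive chaperone Hspa8 at 1479 ± 153 CPM, Hspb1 at 964 ± 156 CPM and Dnajb1 at 783 ± 172 CPM. Hspa1a and Hspa1b are near-identical copies, so their separate counts are uncertain. Genes of the barrier stress list had a median of 2.28 CPM, with Krt16 at 108 ± 44.4 CPM, Krt6a at 103 ± 34.8 CPM and S100a8 at 8 counts in replicate 1 and 0 in replicate 2. Proliferation genes were detected, with 14 of 14 at 1 CPM or more in both libraries. Mki67 stood at 125 ± 36.6 CPM, Top2a at 102 ± 44.3 CPM and Birc5 at 7.68 ± 2.20 CPM. Of 65 replication-dependent histone genes, whose mRNAs lack poly(A) tails, 54 reached 1 CPM in both libraries, with H1f2 at 197 ± 19.9 CPM and H1f3 at 103 ± 37.6 CPM.

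The single most abundant RNA was the small nuclear RNA Rn7sk, which sequesters the elongation kinase, at 21125 ± 1491 CPM. It was followed by Ahnak at 11665 ± 992 CPM, the mitochondrial COX1 at 9544 ± 932 CPM, the translation factor Eef1a1 at 7252 ± 617 CPM and the nuclear RNA Malat1 at 6397 ± 1253 CPM. The remaining genes of the top 15 were Krt5, Actb at 5039 ± 345 CPM, Egr1, Selenop at 4811 ± 409 CPM, Col1a1, the uncharacterised LOC118568312 at 3767 ± 850 CPM, Fos, Fosb, Dsp and Col3a1. Cytosolic ribosomal protein genes had a median of 184 CPM over 89 genes, with Rpl7 at 1144 ± 7.32 CPM and Rpsa at 1126 ± 72.7 CPM. The 37 mitochondrial genes held 1.84% of counts in replicate 1 and 1.51% in replicate 2. Both mitochondrial rRNA genes were higher in replicate 2 by the exact binomial test, mt-Rnr2 at a log2 ratio of 1.03 and mt-Rnr1 at 1.28, with edgeR adjusted p of 0.452 and 0.235. Ribosomal RNA had been removed by hybridization, and a difference in that removal cannot be told apart from one in RNA level. Among the 13 mitochondrial genes that encode proteins, levels lay in separate ranges. COX1, ND1, ND2, ND4, ND5, ND6 and CYTB had 545 to 6177 CPM per kilobase, while COX2, ATP8, ATP6, COX3, ND3 and ND4L had 1.43 to 25.4 CPM per kilobase. For 5 of these 6 low genes, an annotated nuclear transcript matched at 99.7 to 100% identity over 90% or more of the gene.

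**Figure D2:**
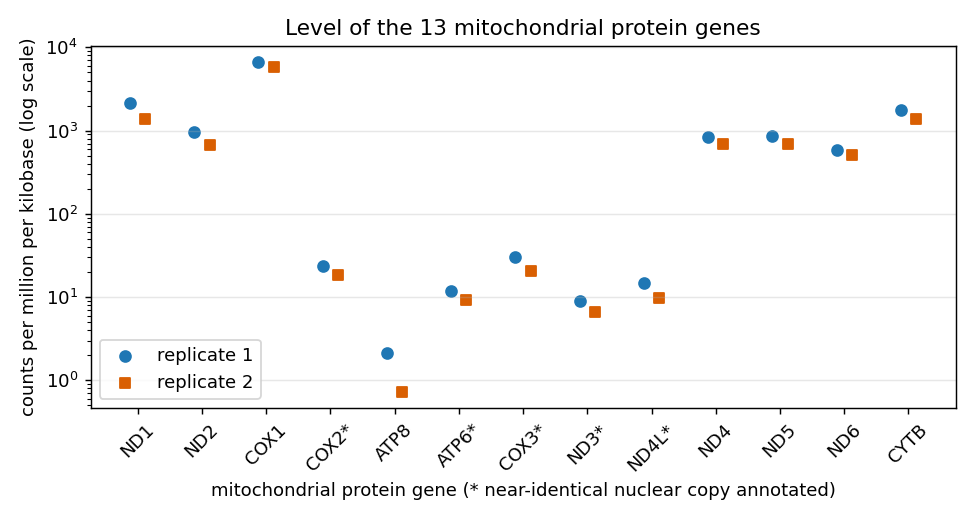
CPM per kilobase of deposited gene length (log axis) for the 13 mitochondrial protein genes in replicate 1 (circles) and replicate 2 (squares). Genes with an asterisk have an annotated nuclear copy at 98% identity or more over 90% or more of their length, and those 5 together with ATP8 lie at 25.4 or below while the other 7 lie at 545 or above (means of both libraries).

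The second question was how closely the libraries agreed, which sets the precision of the steady-state levels. Both libraries ranked genes alike. Over 23690 genes with 10 or more counts in total, Pearson's r of log2(CPM + 0.5) was 0.988 and Spearman's rho was 0.977, across genes, which are not independent replicates. Of the 15833 genes at 1 CPM or more in both libraries, 88.1% differed by less than 1.5-fold, and the median absolute difference was 0.21 on the log2 scale. Beyond 2-fold lay 395 of them, with 55 higher and 340 lower in replicate 2. The biological coefficient of variation shared by these genes was 18.5% in edgeR. The libraries were not copies of each other. By the exact two-sided binomial test with Benjamini-Hochberg adjustment, 10436 of 23690 genes differed beyond sampling noise, 3993 higher and 6443 lower in replicate 2. This split moved with the scaling, to 5374 higher and 5069 lower with TMM, 5494 and 4977 with DESeq2 size factors, and 975 and 13554 when scaled to the junction list. The binomial test compares these libraries and no condition. Against the spread shared by all 23690 tested genes, a coefficient of variation of 22.7%, edgeR's exact test at an adjusted p under 0.05 left 66 genes, 21 higher and 45 lower in replicate 2.

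**Figure D3:**
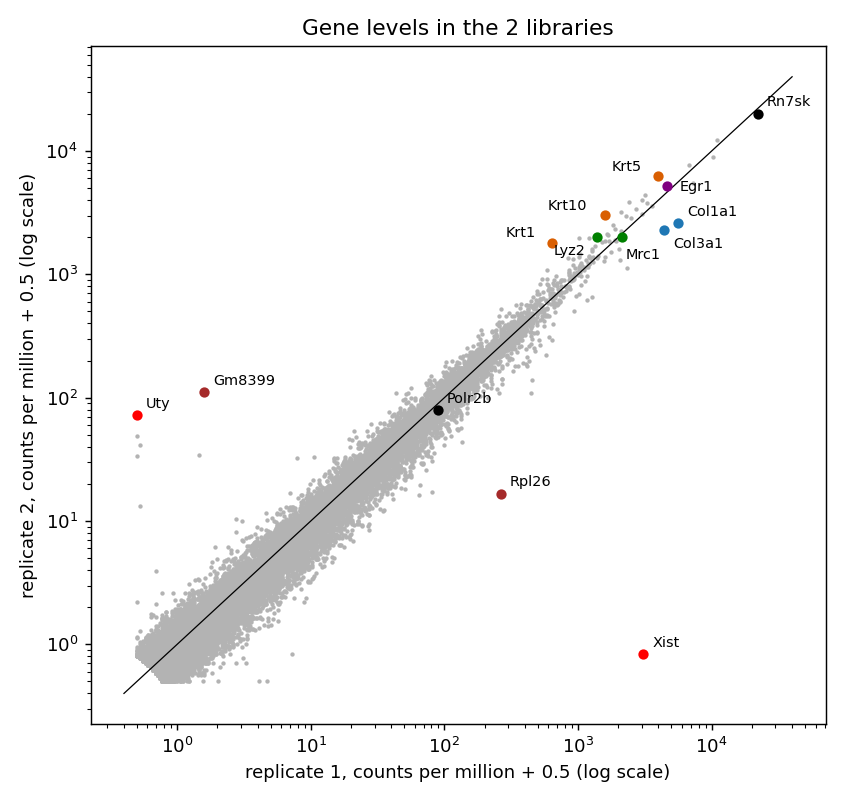
Level of each of 23690 genes in replicate 1 (x axis) and replicate 2 (y axis), as CPM + 0.5 on log axes, with the line of equality and named genes coloured. Xist, Rpl26, Uty and Gm8399 lie far from the line, Col1a1 and Col3a1 lie below it, and Krt1, Krt5 and Krt10 lie above it.

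Sex-linked genes were among the largest differences between the libraries. Xist, the RNA that coats the inactive X chromosome of female cells, had 112587 counts in replicate 1 and 11 in replicate 2. The Y-linked genes Uty, Ddx3y and Kdm5d had no count in replicate 1 and 2394, 1618 and 1113 counts in replicate 2, at least 874-fold, 591-fold and 406-fold higher against a floor of 3 counts. Eif2s3y had 1 and 1378 counts. The labels do not give the sex of the animals or say whether the libraries came from separate animals. Xist RNA almost only in replicate 1 and Y-linked RNA almost only in replicate 2 argue against both libraries coming from 1 animal or 1 pool. The binomial p-values here measure counting error only, and those of edgeR use a spread estimated from these same 2 libraries.

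Outside the sex-linked genes, the fibroblast genes were lower and the differentiated epidermal genes higher in replicate 2. All 10 fibroblast genes were lower by the binomial test, with a median log2 ratio of -0.94, or 1.92-fold, against -0.17 to 0.18 for the central 95% of random lists matched on expression. Col1a1 stood at 5588 CPM in replicate 1 and 2620 CPM in replicate 2, and Col3a1 at 4396 and 2308 CPM. The 6 tested mural genes, all lower at a median of -0.92, and the erythroid list at -1.08 were lower too, as were the endothelial list at -0.48, melanocytes at -0.73 and adipocytes at -0.63. The myeloid list did not stand apart, at a median of -0.09 with 2 genes higher and 6 lower. All 10 spinous genes were higher in replicate 2, with a median of 0.67 and Krt1 at 643 CPM in replicate 1 and 1810 CPM in replicate 2. Of 13 granular and cornified genes 10 were higher and none lower, with a median of 0.36. The junction list had 7 of 11 genes higher and 1 lower, at a median of 0.33.

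Proliferation and replication genes were lower in replicate 2, the library with the lower fibroblast list. All 14 proliferation genes were lower, with a median log2 ratio of -0.69. Mki67 stood at 151 CPM in replicate 1 and 99.5 CPM in replicate 2, and Top2a at 133 and 70.7 CPM. Of 62 tested replication-dependent histone genes, 47 were lower and 3 higher, with a median of -0.70, although near-identical histone genes share reads. Bulge genes were lower as a list, with 9 of 12 lower and a median of -0.43. Krt15 was the 1 higher member, at 2415 and 3868 CPM. Of 11 sebaceous genes 9 were lower and none higher, at -0.53. The Merkel cell list also lay below random lists, at -0.75 over 5 tested genes near the floor. Basal genes had a median of 0.28 with 9 of 12 higher and 2 lower, immediate early genes 0.26 with 12 of 14 higher and none lower, and ribosomal protein genes 0.09 with 48 of 87 higher and 10 lower. Scaling the libraries to the junction list moved log2 ratios by about -0.33, and by less for genes near the floor because of the pseudocount. The spinous and granular medians were then 0.34 and 0.03, and those of the basal, immediate early and ribosomal lists turned to -0.06, -0.08 and -0.23. All 5 lists stayed above their random ranges, which moved with the scaling. The Merkel cell list lay inside the random range without the filter on low counts, at -0.45, and the ribosomal list when random lists were also matched on gene length. In all, 18 of 29 lists lay outside the random range, counting the sex-linked list. Chance gives about 1.45 for lists of unrelated genes. Genes regulated together spread more widely, so the 2 numbers are no test of significance. The other 11 lists lay inside it, with medians of 0.02 for the upper follicle, 0.05 for heat shock, 0.09 for barrier stress, -0.01 for Wnt, Shh and Eda signalling, -0.16 for Schwann cells, -0.21 for telogen quiescence, -0.25 for skeletal muscle and -0.30 for the hair shaft, besides the myeloid and both polymerase lists. Adjusted over the list alone, the exact binomial test called 10 of 10 fibroblast, 10 of 10 spinous, 14 of 14 proliferation, 11 of 12 basal, 8 of 11 junction, 11 of 13 granular, 10 of 12 bulge, 12 of 14 immediate early, 50 of 62 histone and 60 of 87 ribosomal genes. It called 9 of 11 sebaceous, 6 of 6 mural, 5 of 8 endothelial, 6 of 7 melanocyte, 4 of 7 adipocyte, 5 of 5 erythroid and 3 of 5 Merkel cell genes in the same way. Measured against the shared spread with edgeR's exact test, none of the fibroblast, spinous or proliferation genes passed at an adjusted p under 0.05 over all genes, and 3, 2 and 0 of them had an unadjusted p under 0.05. Of the 29 lists without the sex-linked one, 1 erythroid and 1 ribosomal gene passed over all genes. Adjusted over the list alone, edgeR's test called 4 hair shaft and 3 erythroid genes. It called 1 gene each of the spinous, mural, sebaceous, melanocyte and ribosomal lists in the same way.

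**Figure D4:**
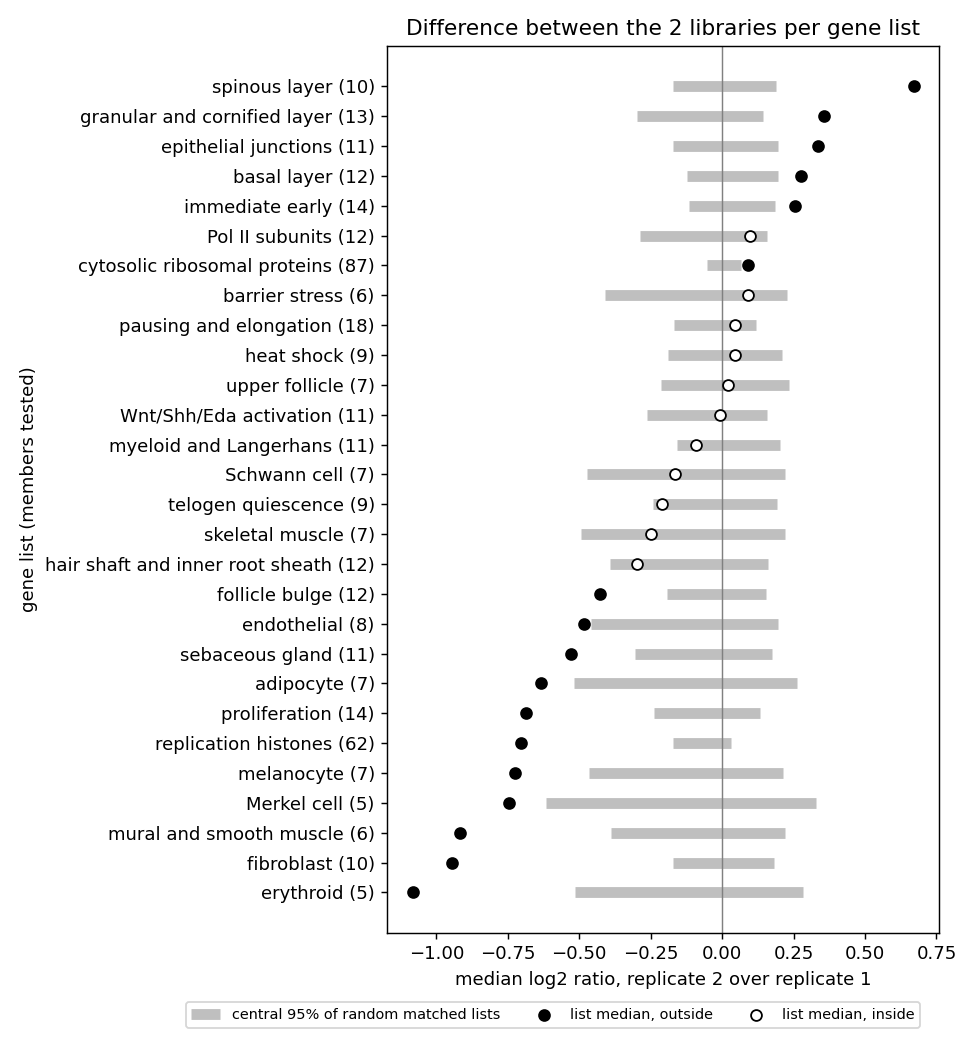
Median log2 ratio of replicate 2 over replicate 1 for each gene list (circles, filled when outside), beside the central 95% of 10000 random lists of the same size matched on expression (grey bars), with the number of tested members in brackets. The spinous list is highest at 0.67, the fibroblast and erythroid lists are lowest at -0.94 and -1.08, and the sex-linked list is left out.

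Among single genes with a mean of 10 CPM or more, the lowest in replicate 2 after Xist was Rpl26, a ribosomal protein gene, at 263 and 16.2 CPM. It was 16.2-fold lower, with a counting interval of 14.9 to 17.7. The acute phase gene Serpina3n was 4.84-fold lower and the replication helicase gene Mcm6 4.09-fold lower. Rpl26, Serpina3n and Mcm6 passed edgeR's exact test, with adjusted p of 1.76e-10, 0.00737 and 0.0284. Lamc3, Retnla, Lepr, Angptl7 and Cntfr were also among the 10 lowest, with log2 ratios from -1.76 to -1.60, and missed that threshold. Of the genes higher in replicate 2, apart from the Y-linked ones, the pseudogene Gm8399, whose transcript is 98.6% identical to Actg1 over 1125 bases, had 40 and 3683 counts and the protease gene Ctse 35 and 1128 counts, and both passed edgeR's exact test with adjusted p of 7.07e-24 and 2.09e-15. Fut2 was 4.26-fold higher with an edgeR adjusted p of 0.0108. Mir6236, Krt1 and Atp10d completed the list with log2 ratios of 1.64, 1.49 and 1.35 and edgeR adjusted p of 0.0865, 0.149 and 0.209.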

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

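Alternatives scaled to the junction list, without Rn7sk and mitochondrial genes, or without the fibroblast and myeloid lists were chosen after seeing the data, and the others before. The number of detected genes stayed within 1.5 times of 15833, except for 9526 at a minimum of 10 CPM, and was 16238 or 16730 with a single library. Agreement (r = 0.988) was 0.980 and 0.991 with pseudocounts of 0.1 and 5, 0.991 without a filter on low counts and 0.985 at 1 CPM or more. The coefficient of variation was 18.9% with library totals only and 23.2% without a filter. The count of genes that differ was 66 in place of 10436 with edgeR's exact test, because that test adds the spread between libraries, and stayed within 1.5 times under the other settings, where the junction scaling moved the share of higher calls from 38.3% to 6.71%. The epidermal excess of 6.01 (log2) was 4.73 with TPM and 6.84 without the fibroblast and myeloid lists, and 5.45 to 6.56 with a single library. The basal excess of 0.46 reversed to -0.97 with TPM and was 0.23 to 0.69 with a single library. The bulge excess of 5.88 was 6.51 and 3.66 with pseudocounts of 0.1 and 5, 5.16 with TPM, and 5.45 to 6.31 with a single library. The cause of these moves was not tested, apart from pseudocounts, which act on genes near the floor. Of the 18 lists outside the random range, 16 stayed outside in every setting that could test them, the Merkel cell and ribosomal lists did not, and the 11 others never left it. The scalings left this count at 18, as they shift genes away from the floor alike, but under the junction scaling, a shift of about -0.33, the basal, immediate early and ribosomal medians reversed to -0.0578, -0.0787 and -0.234. Of the results for single genes and lists under the alternatives, 241 kept direction and side of the threshold, 10 kept direction only and 3 reversed. The junction median under its own scaling, 0 by construction, was left out. Filters do not change the ratio of a single gene, and length matching does not change a list median, so those directions were fixed in advance. TMM and DESeq2 moved the median log2 ratio of all genes by 0.08. No paired analysis was possible because the labels give 1 group. Depth limits the genes near 1 CPM, which rest on about 35 counts, and with 2 libraries a sign-flip test of a level cannot give a p below 0.5.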

Other observations

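The tests of the fibroblast and macrophage transcripts, of the share of fibroblasts and of gene length among mitochondrial genes were chosen only after the result was seen, and the gene lists used only in this part after the data were examined.

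Among the macrophage transcripts, those of resident dermal macrophages were prominent. Of 10 such genes, all passed 10 CPM in both libraries, with a median of 759 CPM. Selenop stood at 4811 ± 409 CPM, Apoe at 2163 ± 91.2 CPM, the transglutaminase gene F13a1 at 1784 ± 114 CPM and Pf4 at 155 ± 10.4 CPM, although Selenop and Apoe are also made by other cells. Mast cell genes were scarce, with Mcpt4 at 4.20 ± 2.31 CPM and Cma1 at 2.92 ± 2.57 CPM, and neutrophil genes had a median of 0.114 CPM, with Csf3r at 29.9 ± 2.70 CPM as the exception. Dermal papilla genes had a median of 1.70 CPM, with Wif1 at 9.72 ± 4.71 CPM. Among inflammatory signals, Nfkbia stood at 646 ± 6.68 CPM, Cxcl2 at 240 ± 73.4 CPM and Il6 at 27.8 ± 18.8 CPM. This list was lower in replicate 2 at a median log2 ratio of -0.63, with 6 of 9 genes lower and 1 higher by the exact binomial test. The dermal papilla list had a median of -0.65, with 3 of 6 genes lower by the exact binomial test, 3 not past it and Rspo3 at 0.32. The list of 13 mitochondrial protein genes had a median of -0.34 with 11 lower. No gene of these 3 lists passed edgeR's exact test adjusted over all genes, and 1 inflammatory gene passed it adjusted over its list alone. The dermal macrophage list lay inside the random range with a median of 0.11 and a mean of -0.04. All 4 tested mast cell genes were lower by the exact binomial test.

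Transcripts of fibroblasts and macrophages were among the most abundant in a fraction sorted for GFP in the keratin 14 lineage. A single admixed source of fixed composition and unchanged expression per cell would move both lists alike. The median log2 ratio of the fibroblast list lay below that of the myeloid list. The difference was -0.8521 (two-sided permutation p = 0.0034 over 21 genes, which are not independent). This argues against such a source only where expression per cell was the same in both libraries, which was not measured. The p-value holds no error between libraries. Fibroblasts and macrophages, or their RNA, collected with the sorted cells are left open, since 19 of 20 further genes of these cells stood at 1 CPM or more in both libraries but so did all 8 endothelial and all 7 Schwann cell genes, and the test therefore decides nothing. Free RNA, whole cells, autofluorescent cells and GFP expressed outside the keratinocyte lineage stay open, and were not tested, since neither GFP nor Cre is among the counted genes. Which of these genes keratinocytes also express was not measured here.

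The fibroblast list was 1.92-fold lower in replicate 2. GC content and gene length are argued against as the whole cause, since the median of -0.94 was -0.9544 after the GC trend was removed and -0.9497 after the length trend was removed, each below the random range. Depth differed by 1.10-fold. With the deeper library thinned to the total of the other, the median was -0.9446, below the random range of -0.17 to 0.18. The difference stayed at equal totals. CPM already scale for the total, so random thinning hardly moves the ratio of abundant genes. This outcome was fixed in advance, and the test cannot decide on depth. A smaller share of fibroblasts in replicate 2 remains a candidate cause. The 10 fibroblast genes that encode no structural matrix protein had a median of -0.6238, below the random range of -0.30 to 0.16. Of these, 9 were lower by the exact binomial test and none passed edgeR's exact test. The pan-myeloid list lay inside its range at 0.09. The fall was not particular to fibroblasts, as the mural, erythroid, endothelial, melanocyte and adipocyte lists also lay below their ranges. The skeletal muscle and Schwann cell lists lay inside theirs. The libraries also differ in Xist and Y-linked RNA, so sex and any other difference between the animals is open and untested, and cannot be separated from the library with 1 library of each kind.

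The 6 low mitochondrial genes COX2, ATP8, ATP6, COX3, ND3 and ND4L lie next to each other in the file between COX1 and ND4. Reads shared with a near-identical nuclear copy, and then not counted, are a candidate cause, as 5 of the 6 have an annotated nuclear copy at 98% identity or more over 90% of their length and none of the 7 other genes has one (Fisher's exact test, two-sided p = 0.00466, which treats neighbouring genes as independent). The case is left open by ATP8, whose best annotated match was 81.4% identical, by the abundant COX1 and ND4, whose copies fall short at 97.6% identity over 100% and 100% identity over 63.6% of the gene, and because how reads with several places were treated is not given in the sources used here. A lower abundance of short genes in the library stays open too, since the low genes have 204 to 784 bases and 6 of the 7 others 957 to 1824 bases, with ND6 at 519 bases as the 1 exception. No biological explanation was tested, as the design gives none.

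Rpl26 and Gm8399 differed in opposite directions, with 263 and 16.2 CPM against 1.09 and 110.0 CPM in replicates 1 and 2, and their reference transcripts gave 0 alignments to each other. The Gm8399 transcript, annotated as a pseudogene, was 98.6% identical to Actg1 over 1125 aligned bases.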
